A study of Homo sapiens with 6 samples.

How the data were processed

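The labels describe 6 RNA libraries of cells labelled MCF-7, grouped by their titles into NC (n = 3) and LINC00365 overexpression (n = 3). Per the labels' protocols, total RNA was purified on silica columns and libraries were made with the ScriptSeq Complete kit, which removes ribosomal RNA and keeps the strand of origin. Whether the counting used strand is not given in the sources used here, nor are the aligner, the counting program or the annotation release. Per the submitters' processing notes the genome build was GRCh38, also called hg38. The treatment label of the NC libraries calls them normal cells, and no label names a vector or mock control.

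The authors deposited read counts per gene, as whole numbers that sum to a different total in each library, and FPKM values beside them, per the file headers. For every value above 0, within a tolerance of 0.001%, the deposited FPKM is proportional to the count divided by the library's total and by the gene's whole span, introns included, so these FPKM understate genes with long introns relative to others. Each library's own table held the same counts as the table of all libraries. Of the 19936 genes, 19926 matched GENCODE release 29 by Ensembl identifier, 98% of these with the same start, end and strand, and 99.7% of all genes were protein-coding. The spans of 6546 genes (32.8%) overlap another gene of the table, and reads in such overlaps, like those of near-identical copies, are uncertain. No read was counted for 3727 genes.

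Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10), scaled by TMM, and fitted with group as the only term by glmQLFit and glmQLFTest, and p-values were adjusted by the Benjamini-Hochberg method over 12478 genes. The threshold was an adjusted p under 0.05, and genes changed at least 2-fold were also counted. The standard error of a log2 fold change is its size divided by the square root of F. CPM values use the TMM-scaled library sizes. Tested on simulated counts for these 12478 genes with 200 changed genes, the fit recovered 24% of genes changed 1.25-fold, 80% at 1.5-fold, 88% at 2-fold and 100% at 4-fold, with 3 false calls among 149. In a second simulation camera called a seeded list of 20 genes raised 1.5-fold, and 7 of 100 random lists had p under 0.05. Genes were simulated independently, so this does not test camera on lists of correlated genes.

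Before the data were examined, 25 gene lists were fixed: glycolysis and lactate, HIF-1 and hypoxia targets, HIF pathway components, nuclear-encoded OXPHOS, mitochondrially encoded genes, TCA cycle, estrogen response, luminal epithelial genes, EMT, cell cycle, p53 targets and apoptosis, interferon response, NF-kB, unfolded protein and ATF4 stress, cholesterol synthesis, MYC targets, immediate early genes, heat shock, ribosomal proteins, histones, noncoding RNAs, and markers of fibroblasts, endothelium, blood and immune cells, and basal-like mammary lines. Some genes stand in more than 1 list, such as ATF3 and HSP90AA1. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 with adjustment over the 24 lists that had tested members. Beside it, camera with an estimated correlation was run, and fry, whose p tests whether a list's genes move, on balance, one way. Named genes were set by rule: LINC00365 and HIF1A; the 8 largest rises and 8 largest falls among genes past the threshold with non-overlapping groups and a mean log2 CPM of at least 1; and from each list up to 4 members past the threshold by smallest adjusted p, or the 2 highest expressed where none passed. Other genes named in the text, including ESR1, PGR, TFF1, STC2, CCND1, COL1A1, THY1, BST2, SLC2A1, TPI1, HK1, RACK1, ALDOA, VIM and the genes of lists added later, were chosen after their values were seen.

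Totals of 14354224 to 17286519 counts per library and a common biological coefficient of variation of 8.56% set the precision. Correlations of log2 CPM were 0.9896 to 0.9941 within groups and 0.9636 to 0.9723 between them. Counts of libraries of the same group differed by a chi-square of 4.74 to 13.6 per degree of freedom, above sampling noise, so each was used as its own replicate. A group with 0 reads was given a floor of 3 counts over the group, and with 1 to 3 reads a ratio of scaled counts with an exact 95% binomial interval. With 3 libraries against 3, an exact permutation test of a single value cannot give a two-sided p under 0.1, and none was used for a call.

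Alternatives were DESeq2 size factors, total count scaling, no filter beyond a nonzero total, at least 50 counts in at least 3 libraries, protein-coding genes only, the replicate number as a block, each library left out in turn, the DESeq2 1.42.0 Wald test, and limma on log2(FPKM + 1) and log2(FPKM + 0.1). Added after seeing the data were TMM factors without the genes changed at least 2-fold, a per-library correction for transcript length and GC content (mgcv 1.9.3), and camera with the interferon list and the genes changed at least 2-fold left out of the background. Bootstrap intervals of list medians used 10000 resamples of the members. LINC00365 itself was not analysed here.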

Results

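RNA sequencing was carried out on 6 libraries from cells labelled MCF-7, an established human breast cancer cell line that is usually described as luminal and estrogen receptor positive. The labels placed 3 libraries in a control group named NC and 3 in a group with overexpression of LINC00365, a long intergenic noncoding RNA. Read counts were given for 19936 genes, of which 99.7% were protein-coding. The NC libraries held 17286519, 17134538 and 14354224 counts, and the overexpression libraries 16219750, 17009279 and 15449538. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Group levels are given as CPM (counts per 1000000 counts of the scaled library), mean ± SD with n = 3, and fold changes as overexpression over NC.

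The comparison of LINC00365 overexpression with NC addresses the question in the study's title, which concerns LINC00365, HIF-1α and the Warburg effect, the use of glycolysis by tumor cells in the presence of oxygen. GENCODE release 29 places LINC00365 (ENSG00000224511) on the minus strand of chromosome 13, from 30103178 to 30108875 in GRCh38, where 0 other annotated genes overlap it. Its level was not analysed here, so these values do not check the overexpression, and the group is named as the labels name it. HIF1A (ENSG00000100644, chromosome 14, 61695513 to 61748259), which encodes the oxygen-regulated subunit of HIF-1, stood at 463 ± 49.1 CPM in NC and 426 ± 28.6 CPM with overexpression. Its log2 fold change of -0.12 (SE 0.084) did not pass the test (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.297). Only RNA was measured, so these libraries do not give the level of the HIF-1α protein or the use of glycolysis.

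Genes of the antiviral interferon response rose in the overexpression libraries by more, in the median, than those of any other list fixed before the data were examined. All 26 members of the fixed interferon list were higher, each at least 2-fold, with a median log2 fold change of 4.23. The smallest rise was that of BST2, at 1.07. IFIT3 and IFIT1, which bind viral RNA or its translation complexes, rose from 36.4 ± 2.05 to 902 ± 7.45 CPM and from 39.8 ± 2.09 to 862 ± 43.2 CPM. OAS2 (ENSG00000111335, chromosome 12, 112978395 to 113011723), a double-stranded RNA sensor that makes 2',5'-oligoadenylates, went from 0.476 ± 0.216 to 286 ± 13.5 CPM, and the dynamin-like GTPase MX2 from 1.19 ± 0.0315 to 241 ± 12.3 CPM. Their log2 fold changes were 4.63, 4.44, 9.22 and 7.66, with edgeR adjusted p between 2.97e-13 and 1.21e-12. The list took 0.136% to 0.148% of all counts in the NC libraries and 1.38% to 1.41% in the overexpression libraries. All 26 members also passed when adjusted over the list alone, and the call held in camera with an estimated correlation (adjusted p = 2.66e-04).

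**Figure D1:**
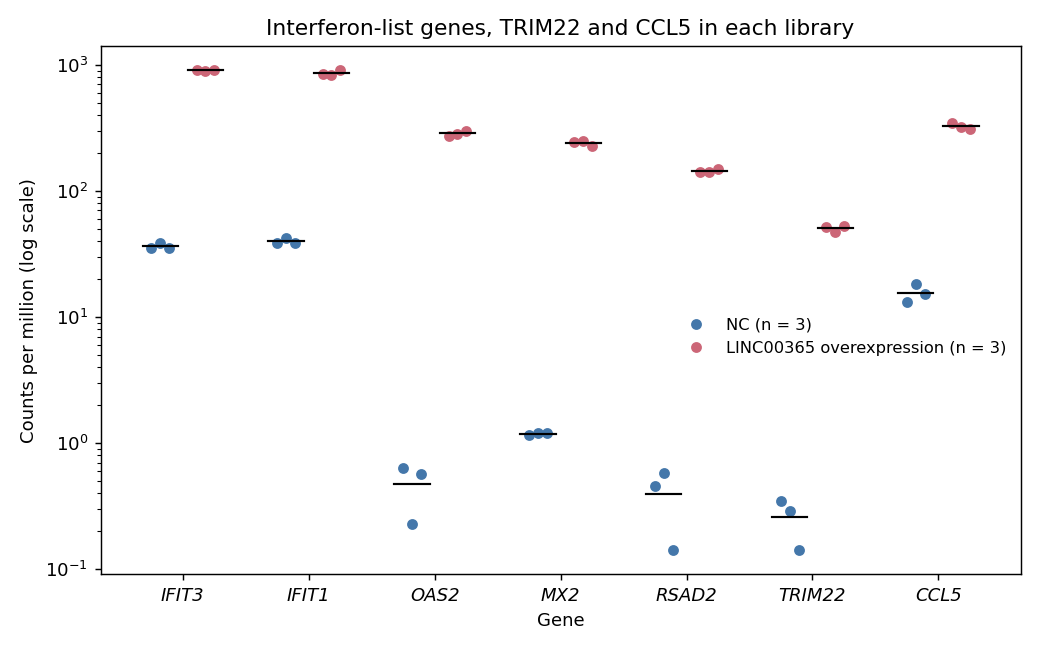
CPM (log scale) of 5 interferon-list genes, TRIM22 and CCL5 in each of the 6 libraries; points are libraries and black lines are group means (n = 3 per group). In all 7 genes the overexpression libraries lie above the NC libraries, for IFIT3 at a mean of 902 against 36.4 CPM.

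Of the 8 largest rises by the fixed rule, 4 were members of the interferon list, XAF1, OAS2, RSAD2 and MX2. XAF1, a pro-apoptotic interferon target, had 0 reads in the NC libraries and 175 to 209 in each overexpression library, which makes it at least 193-fold higher against a floor of 3 counts over the NC group. GCA, a calcium-binding protein named for granulocytes, also had 0 NC reads and was at least 71.5-fold higher. IFNB1 (ENSG00000171855, chromosome 9, 21077105 to 21077963), the gene of interferon beta, had 2 reads in the NC libraries together and 1071 in the overexpression libraries, a ratio of 540 after scaling (95% exact interval 149 to 4460). The antiviral gene SAMD9L had 2 against 918 reads, a ratio of 463 (interval 128 to 3820). These intervals and floors cover counting error only. RSAD2, which encodes viperin, rose by 8.43 on the log2 scale to 143 ± 3.96 CPM, and TRIM22 by 7.53 to 50.6 ± 3.17 CPM, with edgeR adjusted p of 2.4e-12 and 1.09e-11.

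Large falls were few. The largest was in MMP3 (ENSG00000149968, chromosome 11, 102835801 to 102843803), a secreted matrix metalloproteinase, from 19.1 ± 6.29 to 4.84 ± 0.537 CPM (log2 fold change -1.97, SE 0.23, edgeR adjusted p = 5.89e-05). MMP12, a macrophage-type elastase gene, fell from 5.27 ± 0.75 to 2.53 ± 0.316 CPM, and CPA4, a carboxypeptidase gene, from 13.6 ± 3.46 to 6.64 ± 0.746 CPM. PDXP, RNF157, LNP1, CHCHD10 and TSPOAP1 fell by log2 values of -1.24, -1.22, -1.15, -1.13 and -1.11. Their edgeR adjusted p lay between 0.00165 and 0.0224, and CHCHD10 did not pass with limma on FPKM (adjusted p = 0.0585 and 0.0507). TSPOAP1, at 17 to 67 reads per library, did not keep its call without NC replicate 2 (edgeR adjusted p = 0.118), overexpression replicate 2 (0.0797) or overexpression replicate 3 (0.0654). It also did not pass with limma on FPKM (adjusted p = 0.0943 and 0.0671).

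In all, 2192 genes were higher and 1838 lower with overexpression among 12478 tested (edgeR quasi-likelihood test, adjusted p under 0.05). The rises were larger than the falls. At least 2-fold differences were seen for 477 of the higher and 22 of the lower genes, and the median log2 fold change was 0.53 among the higher and -0.35 among the lower. The groups did not overlap in 5725 genes, or 45.9%, against 10% by chance. The first principal component of log2 CPM held 72.7% of the variance and separated the groups. The number of lower genes was 1172 without overexpression replicate 1 and 1087 without overexpression replicate 2. Genes lower at least 2-fold numbered 12 without overexpression replicate 2 and 6 with the stricter filter of at least 50 counts in 3 libraries. The 2-fold counts came to 119 higher and 1 lower when limma was run on log2(FPKM + 1), a scale that understates the change of genes with low values; the test and the unit differ there too.

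**Figure D2:**
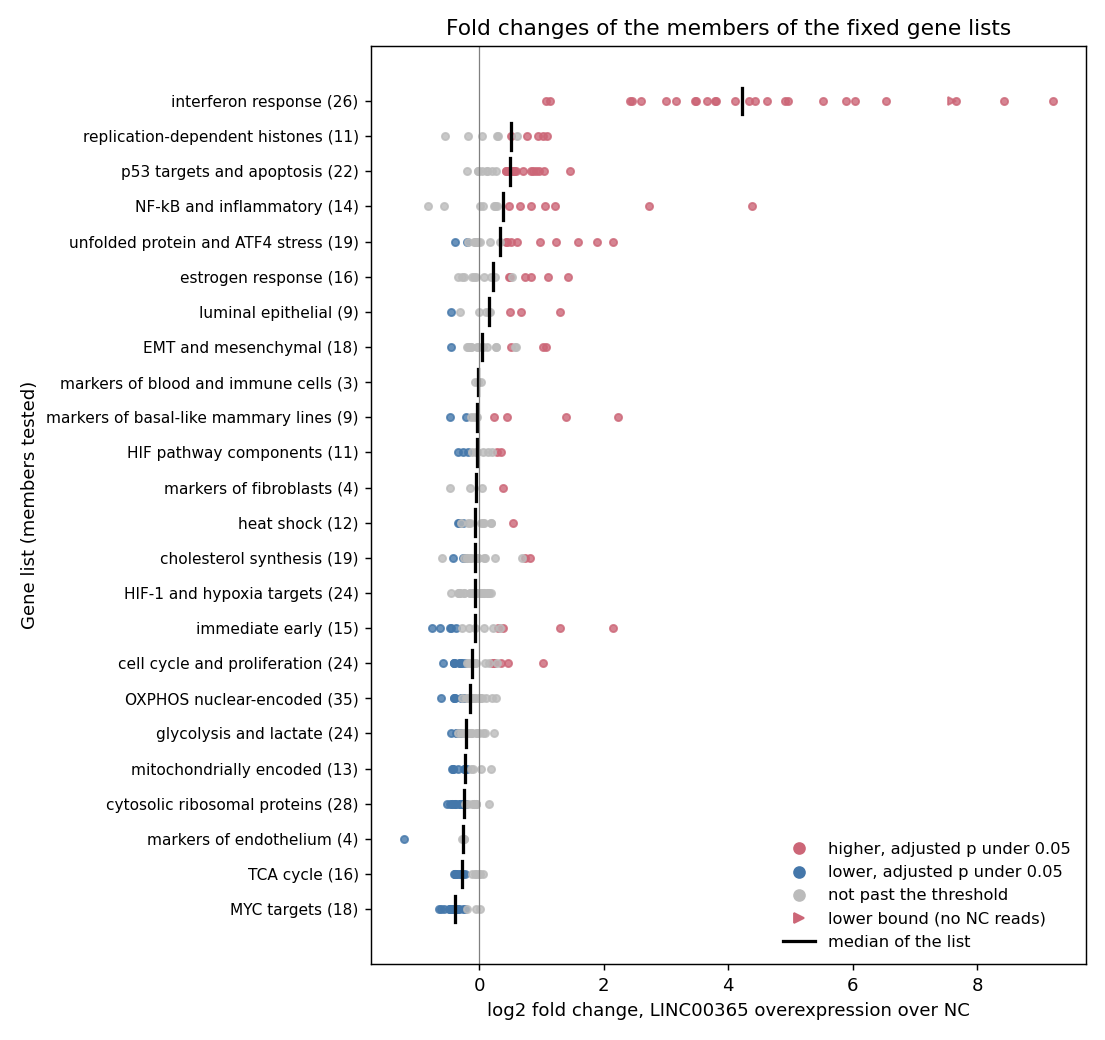
Log2 fold changes (horizontal axis) of the tested members of 24 fixed gene lists (vertical axis, with the number tested), 1 point per gene, coloured by direction where the edgeR adjusted p is under 0.05; black bars are list medians and a triangle marks a lower bound. The interferon list has a median of 4.23, and every other list's median lies between -0.40 and 0.51.

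Enzymes of glycolysis gave a small fall, and its call as a list depended on single libraries. Of 24 glycolysis and lactate genes, 6 were lower, 0 were higher and 18 did not pass, with the same counts adjusted over the list alone, and the median log2 fold change was -0.22. DESeq2 called 8 lower and 0 higher, and 10 lower and 0 higher were at an unadjusted p under 0.05 in edgeR. LDHA, which converts pyruvate to lactate, fell from 2898 ± 297 to 2242 ± 252 CPM (log2 fold change -0.37, edgeR adjusted p = 0.0091). LDHB fell from 1284 ± 77.9 to 1004 ± 41.8 CPM, the muscle-type phosphofructokinase PFKM from 164 ± 13.6 to 120 ± 4.12 CPM and the enolase ENO1 from 1758 ± 149 to 1423 ± 86.3 CPM. LDHA, LDHB, PFKM and ENO1 kept their calls in edgeR with any single library left out. TPI1 and HK1 were the other members that fell, by 0.30 and 0.32 on the log2 scale. The glucose transporter SLC2A1 stood at 332 ± 132 and 300 ± 42.7 CPM and did not pass (edgeR adjusted p = 0.631). ALDOA is uncertain, because the symbol stands on 2 rows with overlapping spans at 5.86 and 5.46 CPM. The list passed in camera (adjusted p = 0.0403) but not with an estimated correlation (adjusted p = 0.787 with an estimated correlation). It also did not pass in camera without NC replicate 3 (adjusted p = 0.26, mean log2 fold change -0.05), overexpression replicate 2 (0.0802) or overexpression replicate 3 (0.088), or with the stricter filter (0.054), nor in fry (adjusted p = 0.295).

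None of the 24 tested targets of HIF-1 and hypoxia passed in either direction by edgeR, adjusted over all genes or adjusted over the list alone. At an unadjusted p under 0.05 the count was also 0, as it was with DESeq2. The median log2 fold change was -0.08 (camera adjusted p = 0.616). The list was spread widely among the NC libraries: its mean log2 level relative to the 6-library mean was -0.57, -0.00 and 0.60 in NC replicates 1 to 3, against 0.24, -0.15 and -0.12 in the overexpression libraries. NDRG1, a hypoxia-induced gene, ranged from 274 to 894 CPM within NC and averaged 551 ± 316 CPM there, against 462 ± 121 CPM with overexpression. BHLHE40, a transcriptional repressor, stood at 571 ± 166 and 597 ± 93.2 CPM. The mean log2 fold change of the list was -0.32 without NC replicate 1, where camera called it (adjusted p = 0.0242), and 0.25 without NC replicate 3 (adjusted p = 0.326). With all 6 libraries it was not called with an estimated correlation either (adjusted p = 0.9 with an estimated correlation).

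**Figure D3:**
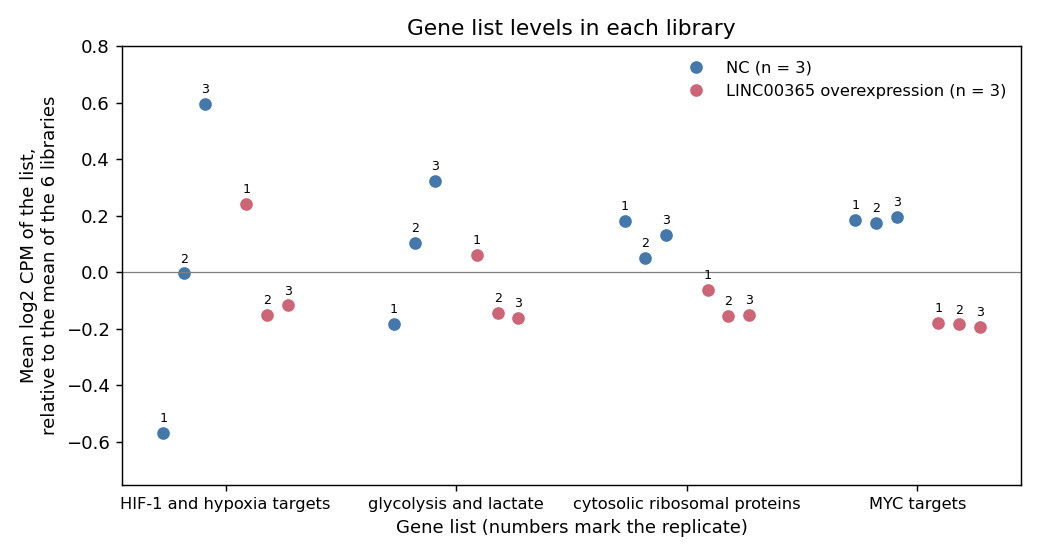
Mean log2 CPM of the members of 4 gene lists in each library, relative to the mean of the 6 libraries (vertical axis); points are libraries, numbered by replicate. The NC libraries span -0.57 to 0.60 for the hypoxia list, while the groups separate for the ribosomal protein and MYC lists.

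Components of the HIF pathway went both ways, with 2 of 11 higher and 3 lower, also when adjusted over the list alone. The coactivators CREBBP and EP300 rose by 0.34 and 0.28 on the log2 scale, from 85.2 ± 8.71 to 108 ± 6.88 CPM and from 144 ± 9.65 to 175 ± 11.4 CPM. The partner subunit ARNT fell from 91.8 ± 3.23 to 76.8 ± 1.18 CPM (log2 fold change -0.26, edgeR adjusted p = 0.0118), the chaperone HSP90AA1 by 0.35 and RACK1 by 0.19. The calls of ARNT (edgeR adjusted p = 0.0621 without overexpression replicate 2) and of EP300 (0.0504 to 0.0642 without NC replicate 1, overexpression replicate 1 or overexpression replicate 2) were lost when single libraries were left out. The list's median log2 fold change was -0.045, its mean 0.001, and camera gave the direction down without a call (adjusted p = 0.735).

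Targets of MYC, a transcription factor that drives growth, fell in 15 of 18 cases and rose in 0 (16 lower adjusted over the list alone), with a median log2 fold change of -0.40. The polyamine enzymes ODC1 and SRM fell from 365 ± 34.7 to 233 ± 15.2 CPM and from 72.4 ± 7.25 to 47 ± 0.753 CPM. CAD, an enzyme of pyrimidine synthesis, and DKC1, a pseudouridine synthase, fell by 0.57 and 0.47 on the log2 scale. MYC itself fell from 499 ± 14.5 to 386 ± 16.8 CPM (log2 fold change -0.37, edgeR adjusted p = 0.000992). Cytosolic ribosomal protein genes were lower in 18 of 28 cases and higher in 0 (20 lower adjusted over the list alone; median -0.26). DESeq2 called 15 MYC targets and 19 ribosomal protein genes lower, edgeR at an unadjusted p under 0.05 gave 16 and 20, and neither gave any higher. RPLP0 fell from 3110 ± 60.7 to 2174 ± 98.8 CPM, and RPL5, RPL3 and RPS2 by 0.44, 0.39 and 0.40 on the log2 scale. Camera called both lists (adjusted p = 9.42e-06 and 7.14e-05), and fry called both down (adjusted p = 4.19e-05 and 0.0214). Neither was called in camera with an estimated correlation, at adjusted p = 0.0709 with an estimated correlation for MYC targets and adjusted p = 0.709 with an estimated correlation for ribosomal proteins.

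Nuclear-encoded OXPHOS genes were lower in 11 of 35 cases, mitochondrially encoded genes in 9 of 13 and TCA cycle genes in 10 of 16, with 0 higher in each, the same counts adjusted over the list alone, and medians of -0.16, -0.24 and -0.28. DESeq2 gave the same counts, and edgeR at an unadjusted p under 0.05 gave 16, 9 and 10 lower and 0 higher. ATP5F1B and ATP5F1A, the beta and alpha subunits of the ATP synthase catalytic core, fell from 1215 ± 54.1 to 916 ± 13.3 CPM and from 409 ± 25.9 to 309 ± 3.42 CPM, and ATP5MC1 and ATP5PB fell by 0.62 and 0.40 on the log2 scale. Citrate synthase, CS, fell from 211 ± 11.5 to 161 ± 9.45 CPM and the pyruvate dehydrogenase subunit PDHA1 from 178 ± 8.62 to 134 ± 4.1 CPM. SUCLG2 and DLAT fell by 0.39 and 0.37. Among mitochondrial transcripts MT-CYB fell from 1353 ± 109 to 1007 ± 62.1 CPM, and MT-ATP6, MT-CO3 and MT-ATP8 by 0.34, 0.42 and 0.44. Mitochondrially encoded reads made up 3.24%, 3.64% and 3.27% of the NC counts and 2.97%, 2.67% and 3.09% of the overexpression counts. Camera called the OXPHOS, mitochondrial and TCA lists (adjusted p = 0.00863, 0.0309 and 0.0101), and fry called them down (adjusted p = 0.0327, 0.0327 and 0.0272). None was called in camera with an estimated correlation (adjusted p = 0.709 with an estimated correlation for each). The mitochondrial list also did not pass without overexpression replicate 2 (camera adjusted p = 0.0802), and MT-CO3 did not pass with limma on log2(FPKM + 0.1) (adjusted p = 0.0565).

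Among p53 targets and apoptosis genes 14 of 22 rose and 0 fell (15 higher adjusted over the list alone; median 0.50), with 14 higher and 0 lower by DESeq2 and 15 and 0 by edgeR at an unadjusted p under 0.05. The death receptor FAS rose from 66.7 ± 4.23 to 137 ± 5 CPM, the BH3-only gene PMAIP1 from 152 ± 31.8 to 415 ± 49.6 CPM and the initiator caspase CASP8 from 25.1 ± 1.76 to 45.9 ± 0.633 CPM. These 3 are also known as interferon-inducible genes. BTG2, an antiproliferative p53 target, rose by 0.83 on the log2 scale. In the NF-kB and inflammatory list 7 of 14 rose and 0 fell, also when adjusted over the list alone, while DESeq2 called 5 higher and 0 lower and edgeR at an unadjusted p under 0.05 gave 8 and 2. The median log2 fold change was 0.38 and the mean 0.77. The other 7 tested members did not pass, among them CXCL8, IL6, NFKBIA, ICAM1 and TNF, at 0.006, 0.056, 0.29, 0.23 and -0.82. The chemokine CCL5 rose from 15.5 ± 2.58 to 326 ± 18.4 CPM, IL1A from 1.27 ± 0.379 to 8.47 ± 1.95 CPM, and the NF-kB subunits NFKB2 and RELB by 1.06 and 1.21 on the log2 scale. The unfolded protein and ATF4 stress list had 9 of 19 higher and 2 lower, with the same counts adjusted over the list alone. The transcription factors ATF3 and DDIT3 rose from 258 ± 110 to 1143 ± 268 CPM and from 26.3 ± 6.49 to 79 ± 18.5 CPM, and CHAC1 and SLC7A11 by 1.88 and 0.98. Camera called the apoptosis, NF-kB and stress lists (adjusted p = 4.77e-05, 3.06e-05 and 0.0377), and fry called them up (adjusted p = 0.00484, 0.0272 and 0.0272). None was called in camera with an estimated correlation, at adjusted p = 0.388 with an estimated correlation for apoptosis and adjusted p = 0.709 with an estimated correlation for the others. The stress list also did not pass without overexpression replicate 2 (camera adjusted p = 0.0524), with the stricter filter (0.054), on FPKM (0.072 and 0.107) or after the length and GC correction (0.0988).

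Several lists had members moving both ways and no call in camera. Cell cycle genes were higher in 6 of 24 cases and lower in 9 (7 and 10 adjusted over the list alone; median -0.12, camera adjusted p = 0.304). The replication licensing gene MCM5 rose from 97.4 ± 1.69 to 198 ± 30.8 CPM, while the mitotic genes PLK1, BIRC5 and AURKA fell by 0.59, 0.42 and 0.41 on the log2 scale. Immediate early genes were higher in 4 of 15 cases and lower in 5 (6 and 5 adjusted over the list alone). ATF3 and JUNB rose while MYC and DUSP1 fell, the median was -0.08, the mean 0.10, camera gave down (adjusted p = 0.765) and fry gave up (adjusted p = 0.926). In the cholesterol synthesis list 2 of 19 rose and 3 fell, also when adjusted over the list alone. HMGCS1 and MVK rose by 0.81 and 0.74, while DHCR7 and the regulator SREBF2 fell by 0.43 and 0.24. The median was -0.07, the mean 0.002 and camera gave down (adjusted p = 0.616). SREBF2 lost its call without overexpression replicate 1 (edgeR adjusted p = 0.0584) or 3 (0.0623), and with the replicate number as a block (0.0514). Among heat shock genes 1 of 12 rose and 3 fell, also when adjusted over the list alone (median -0.07, camera adjusted p = 0.616). The cochaperone DNAJA1 rose from 262 ± 13.8 to 379 ± 7.96 CPM, and HSP90AA1, HSPD1 and HSP90AB1 fell by 0.35, 0.34 and 0.26. Of 11 replication-dependent histone genes 5 rose and 0 fell in edgeR, also when adjusted over the list alone, at an unadjusted p under 0.05 and with DESeq2 (median 0.51, camera adjusted p = 0.0971). Camera called them without NC replicate 3 (adjusted p = 0.00667) or overexpression replicate 3 (0.0122), with no filter beyond a nonzero total (0.0345), and with the interferon list and the genes changed at least 2-fold left out (0.00234). With all 6 libraries they were not called with an estimated correlation (adjusted p = 0.787 with an estimated correlation). HIST1H2AC, HIST1H2BC, HIST1H4H and HIST1H1C rose by 1.09, 0.94, 1.02 and 0.77. The 13 members of the list of nuclear and structural noncoding RNAs were not analysed here.

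Most genes of the luminal list were at low levels in all 6 libraries labelled MCF-7. ESR1, which encodes estrogen receptor alpha and whose span overlaps another gene, had 0 to 3 reads per library, its target PGR 0 and TFF1 1 to 12. The epithelial cadherin CDH1 had 6 to 14 reads and KRT19 4 to 8. Of the 15 luminal genes 7 averaged under 1 CPM and 12 under 25 CPM, the exceptions being KRT8 and KRT18, at 1440 and 469 CPM over the 6 libraries, and MUC1. The estrogen response list was mixed, with 7 of 22 genes under 1 CPM and 13 under 25 CPM, while STC2 stood at 261 ± 82.4 and 246 ± 17.7 CPM and CCND1 at 118 ± 8.81 and 109 ± 5.61 CPM in NC and with overexpression. MUC1 rose from 21.5 ± 4.88 to 34.3 ± 0.676 CPM with overexpression. By contrast VIM, EGFR, CAV1, MSN and AXL, genes of mesenchymal or basal-type breast cell lines, averaged 341, 343, 241, 545 and 162 CPM. The basal markers KRT5, KRT6A and TP63 were as low as the luminal genes, at 0.324 ± 0.121, 0.214 ± 0.149 and 0.252 ± 0.0925 CPM in NC and 0.307 ± 0.113, 0.558 ± 0.32 and 0.351 ± 0.16 CPM with overexpression. Between the groups, 3 of 9 tested luminal genes rose and 1 fell, also when adjusted over the list alone (median 0.16, camera adjusted p = 0.68). FOXA1 rose by 0.49 on the log2 scale and GATA3 by 1.29 at 13 to 58 reads per library, while EPCAM fell by 0.45. The call of GATA3 was lost without NC replicate 1 (edgeR adjusted p = 0.0532) or overexpression replicate 2 (0.0772), and with limma on log2(FPKM + 1) (adjusted p = 0.0511). That of EPCAM was lost without any one of NC replicate 2 and the overexpression replicates (edgeR adjusted p = 0.0772 to 0.122). It was also lost with the replicate number as a block (edgeR adjusted p = 0.0648) and with DESeq2 (adjusted p = 0.05), which called 3 luminal genes higher and 0 lower. Of 16 tested estrogen response genes 6 rose and 0 fell in edgeR, also when adjusted over the list alone, at an unadjusted p under 0.05 and with DESeq2 (median 0.21, camera adjusted p = 0.12). The list was called up by fry (adjusted p = 0.00484) and by camera with the interferon list and the genes changed at least 2-fold left out (adjusted p = 0.00293), but not with an estimated correlation (adjusted p = 0.684 with an estimated correlation). XBP1, a transcription factor of the unfolded protein response, rose from 148 ± 12.4 to 319 ± 32.3 CPM, the protease PRSS23 from 241 ± 9.74 to 429 ± 16.2 CPM, and NRIP1 and IL20 by 0.49 and 1.42.

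**Figure D4:**
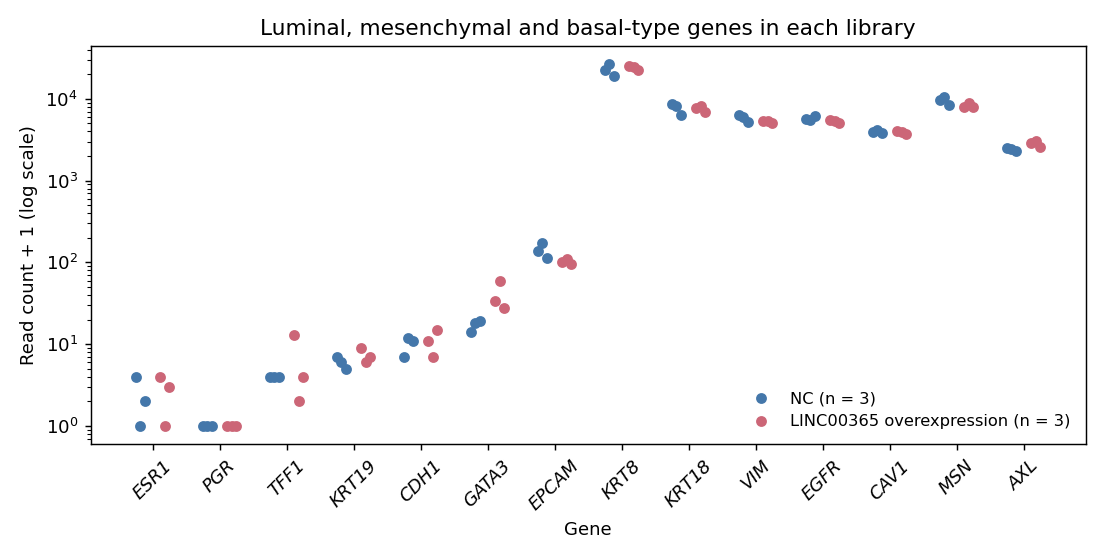
Read counts plus 1 (log scale) of luminal, mesenchymal and basal-type genes in each of the 6 libraries, 1 point per library, coloured by group. ESR1 has 0 to 3 reads per library, while VIM has 5091 to 6356.

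In the EMT and mesenchymal list 3 of 18 rose and 1 fell, also when adjusted over the list alone (median 0.05, camera adjusted p = 0.765). Fibronectin, FN1, rose from 104 ± 23 to 212 ± 26.2 CPM, the repressor ZEB2 from 12.2 ± 2.3 to 25.5 ± 0.474 CPM and the integrin ITGA5 from 531 ± 115 to 757 ± 54.8 CPM, while the gelatinase MMP2 fell from 98.1 ± 7.63 to 71.3 ± 3.55 CPM. Of 9 tested markers of basal-like mammary lines 4 rose and 2 fell, also when adjusted over the list alone; the median was -0.035, the mean 0.37 and camera gave up without a call (adjusted p = 0.359). Fry called the list up (adjusted p = 0.0272), as did camera with the interferon list and the genes changed at least 2-fold left out (adjusted p = 0.049), but it was not called with an estimated correlation (adjusted p = 0.709 with an estimated correlation). The keratin KRT17 rose from 1021 ± 97.5 to 2678 ± 279 CPM, KRT14 from 1.16 ± 0.565 to 5.46 ± 0.891 CPM and ANXA1 by 0.45 on the log2 scale, and S100A4 fell by 0.47. Of 3 tested blood and immune markers 0 passed in edgeR, in DESeq2 or at an unadjusted p under 0.05 (median -0.02, camera adjusted p = 0.768). Of these, SRGN, which many cell types express, stood at 371 ± 38.1 and 352 ± 15 CPM and CD19 at 4.11 ± 1.3 and 4.11 ± 0.616 CPM. Of the fibroblast markers COL1A1 stood at 167 ± 24.7 and 172 ± 23 CPM and THY1 at 25.3 ± 2.64 and 22.7 ± 1.67 CPM. Of 4 fibroblast markers tested 1 rose, PDGFRB, by 0.38, and of 4 endothelial markers 1 fell, CDH5, by 1.22 on the log2 scale at 7 to 29 reads per library, with the same counts adjusted over each list alone. Neither list was called by camera (adjusted p = 0.859 and 0.359), and fry called the endothelial list down (adjusted p = 0.0428), on 4 tested members. That list was not called with an estimated correlation (adjusted p = 0.709 with an estimated correlation). PDGFRB lost its call without NC replicate 1 (edgeR adjusted p = 0.0914), NC replicate 3 (0.0769), overexpression replicate 1 (0.0738) or overexpression replicate 2 (0.132), and CDH5 without NC replicate 1 (0.0639), overexpression replicate 2 (0.066) or overexpression replicate 3 (0.0634).

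Of the 24 lists tested, camera called 10 with the preset correlation of 0.01 and fry called 12. Only the interferon list was called in camera with an estimated correlation. The labels name no library that received a construct without LINC00365, so the groups may differ by more than the sequence expressed.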

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

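The alternatives with TMM factors recomputed, the length and GC correction and camera without the strongest genes were chosen only after the result was seen. Of 1678 alternative values of 99 named genes, 1644 kept their direction and side of the threshold, 33 lost the call, 1 gained it and 0 reversed. Most of these genes were picked for a large change or a small adjusted p in the same data, so their stability does not carry over to all calls. Of all 4030 calls, 2681 were kept without overexpression replicate 2, the fewest of any alternative. The most, 4029, were kept with protein-coding genes only. The interferon list kept its call under every alternative that tested it, with leave-one-out means of 4.61 to 4.75 on the log2 scale. Leaving out single libraries gave 1607 to 2346 higher and 1087 to 1991 lower genes, with 440 to 525 and 12 to 30 of them changed at least 2-fold. The lowest counts of lower genes came without overexpression replicate 2 (1087, 12 at least 2-fold) and replicate 1 (1172). Genes lower at least 2-fold numbered 6 with at least 50 counts in 3 libraries, which tests fewer genes, and 1 with limma on log2(FPKM + 1) or log2(FPKM + 0.1), where genes higher at least 2-fold numbered 119 and 251; these change test, unit and pseudocount together, and the cause was not tested. DESeq2 called 2039 higher and 1818 lower. Camera called 10 lists, 7 to 11 with single libraries left out, and 1 with an estimated correlation; fry called 12, and camera without the strongest genes 12. The mean log2 fold change of the glycolysis list was -0.17 with at least 50 counts (adjusted p = 0.054), -0.18 with an estimated correlation (0.787) or with fry (0.295), and -0.30 to -0.049 with single libraries left out, over adjusted p from 0.000629 to 0.26; the cause was not tested. That of the hypoxia targets ranged from -0.32, without NC replicate 1, to 0.25, without NC replicate 3. The replicate number as a block gave 1724 higher and 1296 lower genes, 3009 of them shared with the 4030 calls without it and 0 called in the opposite direction. Deviations of same-numbered libraries correlated at -0.07, -0.15 and -0.20, and no library matched its own number best. These values show no pairing by number, but they cannot exclude a shared culture or day, which the labels do not give. Quantile normalization and limma without trend, planned for values without counts, were not run, and LINC00365 had no value under any alternative. In the simulation 24% of the smallest changes were recovered, but only 200 of 12478 genes were changed there. The adjusted threshold is less strict when more genes change, as with the 4030 calls here, so that share does not carry over. Small changes can still be missed.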

Other observations

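The gene lists of the next paragraphs were written after the interferon result was seen, as were the tests on the luminal and ribosomal protein genes; the tests on the interferon and glycolysis genes and on the splits of the libraries were written before their results. Genes of antigen presentation rose with the interferon genes. No list test was run on these added lists, so only counts of members are given. Some of their members also stand in the fixed lists, so the same rises are counted again here. DDX58, IFIH1, CXCL10 and ISG15 are in the fixed interferon list, and CCL5 and TNFAIP3 in the fixed NF-kB list. All 17 genes of MHC class I and peptide loading were higher (edgeR adjusted p under the threshold in each), with a median log2 fold change of 1.01. The peptide transporter TAP1 rose from 101 ± 2.68 to 352 ± 32 CPM, the immunoproteasome subunit PSMB9 from 15.1 ± 2.26 to 75.9 ± 3.92 CPM, the peptidase ERAP2 from 3.72 ± 0.728 to 40.1 ± 1.57 CPM, HLA-E from 350 ± 21.5 to 772 ± 55.5 CPM and B2M from 2167 ± 153 to 3521 ± 136 CPM (n = 3 per group). Of 10 tested sensors of foreign nucleic acid and their adaptors 6 rose and 1 fell. The RNA sensors DDX58 (RIG-I) and IFIH1 (MDA5) rose from 37.2 ± 3.13 to 645 ± 4.11 CPM and from 2.51 ± 0.336 to 148 ± 10.9 CPM, EIF2AK2 (PKR) by 1.94 on the log2 scale and TLR3 by 3.91. MAVS, the adaptor of DDX58 and IFIH1, fell by 0.31 on the log2 scale (edgeR adjusted p = 0.0162), TICAM1, the adaptor of TLR3, rose by 0.35 (edgeR adjusted p = 0.0228), and the kinase TBK1 was at 90.5 ± 5.01 and 86.6 ± 2.64 CPM.

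Interferon transcripts themselves were present. Besides IFNB1, the type III interferon IFNL1 rose from 0.143 ± 0.0863 to 9.83 ± 0.85 CPM, and IFNL2 and IFNL3, near-identical paralogs whose reads are uncertain, rose by 3.77 and 2.74 on the log2 scale. IFNA2 and IFNG had 0 reads in all 6 libraries, which allows up to 3 counts over them. Of 9 receptor and JAK genes 2 rose, JAK1 by 0.82 and JAK2 by 1.35. The receptor genes IFNAR2 and IL10RB were barely counted, at 6 to 23 and 10 to 15 reads per library. IFNAR1 stood at 73.2 ± 2.85 and 73.5 ± 4.61 CPM. A list named inflammatory cell death also held apoptosis genes such as CASP7 and CASP10, and apolipoprotein L genes. Among its 14 tested genes 12 rose, including CASP1 (2.95), TNFSF10, which encodes the death ligand TRAIL (4.50), APOL1 (4.41), APOL6 (2.76), MLKL (0.55) and GSDMD (0.50), all as log2 fold changes. GSDME and TNFRSF10A did not pass, at -0.06 and 0.13, and RIPK3, with at most 1 read in a library, was not tested. Of 9 tested chemokines 5 rose, with CXCL10 at 5.53 and CXCL11 at 6.04, while CXCL8 stood at 728 ± 320 and 731 ± 118 CPM (edgeR adjusted p = 0.988). Of 8 feedback regulators 4 rose: USP18 by 5.31, ISG15 by 2.60, TRIM21 by 3.13 and TNFAIP3 by 0.65.

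Within 1 Mb of LINC00365, HMGB1 fell from 528 to 425 CPM (log2 fold change -0.31, edgeR adjusted p = 0.00327). KATNAL1, UBL3, USPL1, SLC7A1 and MTUS2 did not pass, with log2 fold changes of -0.18, 0.07, -0.03, 0.08 and -0.59. Among all tested genes 32.3% passed, so the call of HMGB1 alone does not set this region apart.

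With group labels moved over all 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave 4030 genes in edgeR; the highest of the other splits gave 0 at the adjusted threshold and 761 at an unadjusted p under 0.05, against 5332 for the real split. So few splits cannot give a share under 0.05. Each of the other splits also mixes NC and overexpression libraries, so the difference between them adds to the spread within groups and lowers the count. Those counts are therefore not what libraries without a difference would give.

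The rise of interferon response genes was weighed against cells of another type and against the way the construct was delivered. A mix of blood and immune cells in the overexpression libraries is argued against by the fixed markers, whose median reached at most 0.188 CPM in those libraries. SRGN, also expressed by other cells, nevertheless stood at 352 ± 15 CPM. The markers come from several cell types, so cells of a single type could leave the median low. Singly, PTPRC had at most 3 reads in a library and CD3E and TYROBP had 0, while CD19 stood at 4.11 CPM in both groups. Transcripts of type I and III interferon made by these cells are a candidate source: IFNB1, IFNL1, IFNL2 and IFNL3 together had at least 556 counts in each overexpression library and 7 to 12 in each NC library. Delivery of the construct in place of the LINC00365 sequence cannot be told apart from an effect of LINC00365, because 0 libraries have labels that name a construct without LINC00365.

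Low levels of most luminal genes in all 6 libraries labelled MCF-7 were the next pattern, with KRT8, KRT18 and MUC1 as exceptions; the estrogen response list was mixed. Reads lost where gene spans overlap are argued against for luminal members that overlap no other gene, since these had a median of 0.349 CPM. ESR1 does overlap another gene of the table, so this median does not cover its 0 to 3 reads. Cells with a basal-like or mesenchymal expression state in place of a luminal one stay open: the median of the basal-like list exceeded that of the luminal list by at least 164 CPM in every library, but the medians of 19 of 22 other fixed lists were also above it in every library, so this decides nothing, and KRT5, KRT6A and TP63 were low too. Whether the cells were a changed population of the line or another line was not tested.

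The small falls of the glycolysis and ribosomal protein lists were weighed against scaling and against sequence trends. With scaling factors computed without the genes changed at least 2-fold, the medians were -0.200 for glycolysis (95% bootstrap interval -0.274 to -0.112) and -0.236 for ribosomal proteins (-0.297 to -0.184). The median over all tested genes moved only from -0.003 to 0.016. These values argue against scaling shifted by the genes changed at least 2-fold as the whole cause, and do not cover smaller changes. After correction for transcript length and GC content the list medians were -0.206 (-0.272 to -0.1) and -0.243 (-0.290 to -0.192), the first reaching the bound of -0.1 set for that test. The intervals resample the members of a list, so they do not cover the spread between libraries. Spread between libraries stays open for glycolysis, since NC replicates 1 to 3 stood at -0.18, 0.10 and 0.32 relative to the 6-library mean and the overexpression libraries at 0.06, -0.14 and -0.16, and without NC replicate 3 the mean fold change was -0.05. The glycolysis list may therefore follow the same variation between NC libraries as the hypoxia targets, which span -0.57 to 0.60 there, and a lowering through LINC00365 was not separated from it.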
